A study of Mus musculus with 88 samples.

How the data were processed

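RNA of 44 groups of mouse cells or tissue was hybridised to 88 two-colour Agilent 44K arrays, with 2 arrays per group. The sample was labelled with Cy3 and a common reference with Cy5 on every array, per the labels; the reference pooled RNA of several mouse lines with RNA of 129 ES cells. Dyes were not swapped, so a dye effect common to all arrays cancels only in differences between groups. The arrays lay on 22 slides of 4 and were scanned on 6 days. The deposited scanner files hold spot intensity values in both channels, with the local background, extracted by the authors with Feature Extraction 9.5.1.1 under 1 protocol, per the file headers. The processed intensity columns in the same files were background-subtracted and dye-normalized by that software, per the file headers.

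A table deposited by the authors holds log10 values for 25164 features. Set against the scanner files, 100% of its values were within 0.001 of the log10 processed Cy3 intensity minus the deviation of the log10 processed Cy5 intensity from its mean over the 88 arrays. The scale and direction were thereby found from the values: log10, higher for more sample RNA, and not centred. The column medians ran from 2.09 to 2.27. This table served as an alternative.

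Groups were taken from the labels. The treatment text of the ZHBTc4 samples describes the construct of another line, so the description of ZHBTc4 rests on background knowledge. Both arrays of 5G6GR5 at days 3 to 5 carry the same replicate number in the labels. The names of the iPS lines were not interpreted. Sample RNA was labelled with 2 kits, per the labels: a low-input kit for 5G6GR5, NS1, fibroblasts, iPS lines, EG-1, ES-129.3 and ES-C57BL6.9, and another for the courses N2, ZHBTc4 and PrEn, DC, TS, placenta, F9, P19, ES_129a and ES_129b. EBRTcH3, ES-D3-GL and TGC_8.5-5 had 1 array of each kit.

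Mean spot intensity was background-corrected with the normexp method of limma 3.58.1 (offset 50) in R 4.3.3, and log ratios were loess-normalized within arrays. Before that, spots marked by Feature Extraction as background outliers took the median background of their array. This step was added after the data were seen. On 8 arrays the median absolute deviation of the log ratios without it was under 0.8 of that with it. On these, between 2 and 12 spots per channel lay over 50 intensity units below a local background that reached 65197, against a typical 45.75. The deviation was 0.034 to 0.24 on these arrays, against 0.31 to 0.41 after the step. ES_129a replicate 2, with 2 such spots in Cy3 and 3 in Cy5, had 0.28 against 0.33 after it. All spots that far below the background carried the software's outlier mark. The local background at every spot, as planned, is an alternative. Of 43451 spots, 1417 control spots were left out, as were spots flagged as outliers, and spots of 1 probe were averaged, which left 42006 probes. Saturated spots were kept. A probe was tested if it was well above background in Cy3 on both arrays of at least 1 group, which left 34105 probes.

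The files do not pair the probes with gene names, and none of the tables used here names them. The gene lists and the target genes fixed before the data were examined were therefore not analysed here, and the rule for named genes was applied to probes, limited to at most 2 that rose and 2 that fell per comparison: among probes past the threshold, well above background on every array of both groups and without overlap of the arrays, those with the largest change. The planned mean over the probes of a gene was not run. In place of gene lists, groups of probes were defined after the data were seen, from reference cells and tissue or from another course or treatment than the one tested. They rest on at least 4-fold and adjusted p below 0.05 for the defining source. No probe group was tested on DC against NS1, since their definition involves NS1. A probe not well above background on any array of a group and well above it on every array of the other has only a bound: the fold is given as at least the mean of the bright group over the detection floor of the dim group, from Cy3 values after loess and quantile scaling of the reference channel, which stay open to dye bias.

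Comparisons used lmFit and eBayes of limma on the log2 ratios, with 1 coefficient per group over all 88 arrays (44 residual degrees of freedom), so that groups share 1 estimate of spread. Cell classes were compared on line means: 4 ES, 2 EG, 2 iPS, 2 EC and 4 fibroblast lines (9 residual degrees of freedom). Calls needed a Benjamini-Hochberg adjusted p below 0.05 and at least a 2-fold change. Probe groups were tested with camera (preset correlation 0.01, adjusted over the groups of a comparison) and again with an estimated correlation. The sign of the median and of the test differed, without a call, for PrEn-high probes in N2, fibroblast-high probes in 5G6GR5, P19-high probes in PrEn and 5G6GR5-high probes in P19. Tests were two-sided. On data simulated from these arrays, 98% of probes changed 2.83-fold and 100% changed 4-fold were recovered for N2 day 6 among 34105, with 2 false calls. For fibroblasts 92% and 90% were, with 3 false calls. The simulated lines all had the spread among the 4 ES lines, which the lines of the other classes need not share. The number of overlapping calls given by chance is that of independent lists.

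Replicate numbers were checked as pairs by correlating the differences between the 2 arrays of a group across groups. In ZHBTc4 from 24 to 120 h all 10 pairs of groups correlated above 0.1 (0.17 to 0.78), and the numbers were taken to pair samples. In N2 (11 of 21 pairs above 0.1) and PrEn (7 of 10) the labels name shared runs, which pair the samples. Every group lay within 1 scan day. In the Cy5 channel, which holds the same RNA everywhere, between 35 and 290 probes passed the same test per comparison of groups. Alternatives were processed signals without loess, no background subtraction, Cy3 alone with quantile normalization, scaling between arrays, the authors' table, other filters, smaller fits, slide, kit and replicate blocks, arrays of 1 kit, and leaving out arrays and lines. Figures were drawn with matplotlib 3.10.9.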

Results

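Transcript levels were measured on 88 two-colour arrays of 60-mer oligonucleotide probes, which covered 44 groups of mouse cells or tissue with 2 arrays each. The sample was labelled with Cy3 on every array and set against a common reference RNA in Cy5, so values are log2 ratios of sample to reference. The groups formed 4 time courses of differentiation, P19 cells with and without retinoic acid, 2 neural groups and a panel of undifferentiated and differentiated cell lines. The N2 course followed 129 embryonic stem (ES) cells for 6 days in a serum-free medium used for neural differentiation, with the ES group ES_129b as day 0. ZHBTc4 is an engineered ES line sampled over 120 h with tetracycline; it is known as a line in which tetracycline shuts off the pluripotency factor Oct4. 5G6GR5 is an ES line sampled over 5 days with dexamethasone; it is known for a dexamethasone-activated form of the endoderm factor GATA6. The PrEn course covered 5 days with retinoic acid and dibutyryl cAMP; its labels name no starting cells, and F9 embryonal carcinoma (EC) cells, of the same strain label and medium, served as day 0. The number of arrays per group, 2, limits the precision of every value. The labels tie the 2 arrays of a group to separate differentiation runs in the N2 and PrEn courses; elsewhere they do not state separate cultures for every group, so p-values may measure technical spread alone.

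Between 21741 and 32238 probes per array (median 25800.5) were well above background in Cy3. The log2 ratios of the 2 arrays of a group correlated across probes with a median Pearson r of 0.98, the lowest being 0.91 for the neurosphere cells NS1. No arrays held identical values, and 82 of the 88 arrays correlated best with the other array of their own group. The reference channel correlated at r of 0.987 or more between any 2 arrays, against 0.772 or more for the sample channel. The array files do not pair the probes with gene names, so results are given by probe, and groups of probes are named by the cells in which they were high. With the scanner software's processed signals and no loess, most counts of changed probes were over 1.5 times those given here, such as 10578 for N2 and 12724 for ZHBTc4. With those signals more probes fell than rose in ZHBTc4 (5440 up, 7284 down), in PrEn (3579 up, 4780 down) and in TS cells against ES lines (4774 up, 6954 down), where the counts given here have more up than down. The balance of ZHBTc4 also turned with Cy3 alone (4263 up, 4354 down) and with the authors' table (3972 up, 4037 down), and that of TS cells with the authors' table (3647 up, 3688 down).

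The first 2 principal components of the group means held 24.6% and 16.5% of the variance. The ES, embryonic germ (EG) and induced pluripotent stem (iPS) lines scored from -86.2 (the ES line EBRTcH3) to -49.1 on the first component, a range that also held N2 day 1 (-67.6), and the EC lines F9 and P19 scored -58.3 and -24.3. Fibroblasts and neural cells lay at the high end, at 128.7 for MEF-DR4 and 143.8 for differentiated neural cells (DC). The second component separated the courses: N2 reached a score of 85.8 by day 6, while ZHBTc4 reached -119.9 by 120 h. The score of 5G6GR5 was -58.3 at day 5. On the third component, which held 11.0% of the variance, PrEn day 5 (88.3) and 5G6GR5 day 5 (75.8) had scores well above N2 day 6 (14.9) and ZHBTc4 at 120 h (-63.2).

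**Figure D1:**
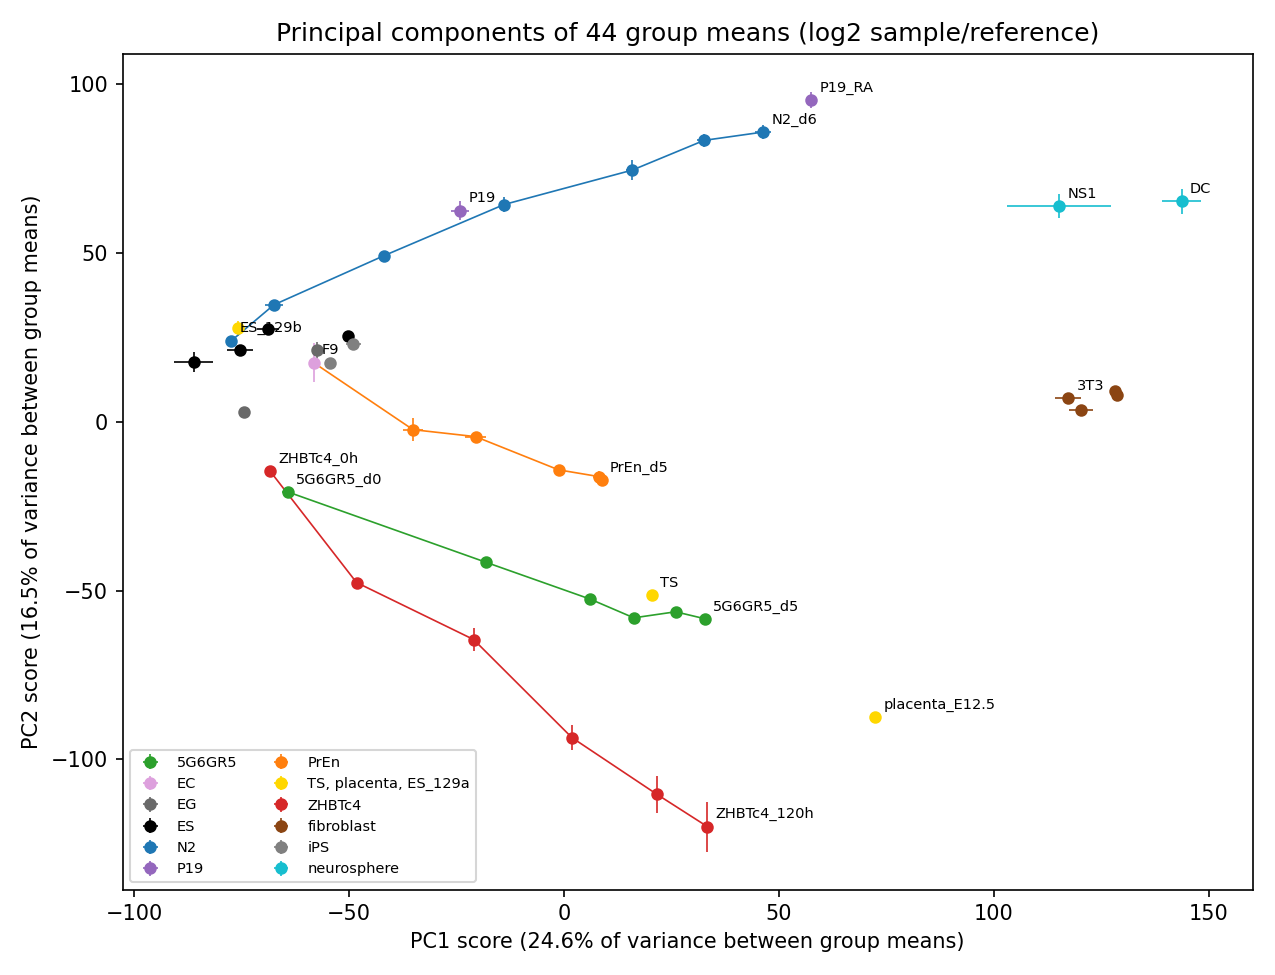
Scores of the 44 group means on the first and second principal components (arbitrary units); points are group means of 2 arrays, bars are the SD of the 2 arrays, and lines join the days of a time course. N2 rises to 85.8 and ZHBTc4 falls to -119.9 on the second component, starting from -14.5 for ZHBTc4 and 24.0 for ES_129b.

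Each probe group was tested only in courses or treatments with which it shares no array. ES-high probes (342) were at least 4-fold lower than in the 4 ES lines in each of trophoblast stem (TS) cells, E12.5 placenta, NS1 cells and fibroblasts. Groups of 171 TS-high, 775 placenta-high, 535 NS1-high and 203 fibroblast-high probes were at least 4-fold above the ES lines in that source and under 2-fold above them in the other sources. A further 221 probes were high in both TS cells and placenta. PrEn-high (125), 5G6GR5-high (62), N2-high (204) and P19-high (164) probes rose at least 4-fold in that course or treatment and were under 2-fold above the ES lines in all 4 sources. The groups were defined after it was seen that no gene names were given.

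In the N2 course the ES-high probes fell together and the NS1-high probes rose. Of the 342 ES-high probes, 310 fell and 9 rose by day 6, with a median log2 change of -3.15 (quartiles -4.15 and -2.12). Of the 535 NS1-high probes, 207 rose and 13 fell, with a median of 0.71 (quartiles 0.14 and 1.56), while 10.0% of all other probes rose. That median was 1.42 with the processed signals and 1.38 with the authors' table. Of the 164 P19-high probes, which rose in retinoic acid treated P19 cells, 102 rose and 11 fell, with a median of 1.66, which was 2.55 with the processed signals and 2.79 with the authors' table. The camera test called all 3 groups, with adjusted p = 3.4e-07, 4.5e-07 and 2.7e-07 with an estimated correlation. In total 3569 probes rose and 2672 fell against ES_129b among 34105 tested, at an adjusted p below 0.05 and at least 2-fold. Of the risers, 405 were not well above background on either ES_129b array and well above it on both day 6 arrays, by a median of at least 3.01-fold among those with a bound over 1, and 358 of the fallers showed the opposite. Probe Z00075427-1 (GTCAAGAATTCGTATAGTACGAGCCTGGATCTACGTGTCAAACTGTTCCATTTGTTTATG) rose from 0.37 ± 0.04 to 7.98 ± 0.56 (log2 ratio, SD, n = 2 each), a 195-fold rise with adjusted p = 9.4e-30. Probe Z00013361-1 (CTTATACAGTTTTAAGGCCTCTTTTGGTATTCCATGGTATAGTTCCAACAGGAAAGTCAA) fell from 1.46 ± 0.01 to -6.44 ± 0.25, 238-fold, with adjusted p = 2.0e-41. The TS-high group (21 rose, 33 fell) had a lower shift than other probes by camera, a call lost with adjusted p = 0.49 with an estimated correlation. The calls of the fibroblast-high group (46 rose, 13 fell) and of the TS and placenta-high group (30 rose, 48 fell) were lost likewise, at adjusted p = 0.557 for each with an estimated correlation. The placenta-high, PrEn-high and 5G6GR5-high groups had no call. Changes accumulated by day: 286 probes were up and 388 down at day 1, 1660 and 1441 at day 3, and 2957 and 2534 at day 5. All arrays of this comparison were scanned on 1 day.

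In the ZHBTc4 course the probes high in both TS cells and placenta rose, and the ES-high probes fell. Of the 221 TS and placenta-high probes, 167 rose and 2 fell by 120 h, with a median log2 change of 2.33 (quartiles 1.03 and 3.59), and 13.1% of other probes rose. Of the 775 placenta-high probes, 246 rose and 32 fell, with a median of 0.33, which was 0.55 with the authors' table and 0.23 with Cy3 alone. The TS-high probes, under 2-fold above the ES lines in placenta, had 44 of 171 risen, 23 fallen and a median of 0.16, with no call by camera (adjusted p = 0.12). Of the ES-high probes, 296 fell and 4 rose, with a median of -2.71. With an estimated correlation, adjusted p = 0.00058 for the TS and placenta-high group, 0.00074 for the placenta-high group and 4.6e-05 for the ES-high group. The P19-high group (7 rose, 37 fell) was called lower, at adjusted p = 0.042 with an estimated correlation. The NS1-high group (27 rose, 94 fell), the N2-high group (8 rose, 53 fell) and the fibroblast-high group (38 rose, 12 fell) lost their calls, at adjusted p = 0.053, 0.13 and 0.45 with an estimated correlation. The PrEn-high and 5G6GR5-high groups had no call. In total 4615 probes rose and 3632 fell against 0 h. Of these, 386 risers were not well above background on either 0 h array and well above it on both 120 h arrays, and 377 fallers the opposite. Probe Z00052446-1 (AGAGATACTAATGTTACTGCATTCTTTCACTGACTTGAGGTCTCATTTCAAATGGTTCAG) rose 229-fold, from -3.00 ± 0.06 to 4.84 ± 0.03 (SD, n = 2 each), with adjusted p = 9.9e-43. Probe Z00074667-1 (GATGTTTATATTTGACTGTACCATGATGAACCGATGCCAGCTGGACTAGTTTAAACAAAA) fell 220-fold, with adjusted p = 1.3e-38. At 24 h 1114 probes were already up and 1525 down, and at 72 h 2958 and 2905. Across probes, the change at 120 h correlated with placenta against ES lines at Pearson r = 0.61 and with TS against ES lines at r = 0.51, and with fibroblasts against ES lines at r = 0.44, where probes are not independent replicates. The correlation with placenta was 0.23 at 24 h. These arrays, too, were scanned on 1 day.

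In the 5G6GR5 course falls outnumbered rises, and the ES-high probes fell early. Of the 342 ES-high probes, 295 fell and 2 rose by day 5, with a median of -3.00. Of the 125 PrEn-high probes, 56 rose and 20 fell, with a median of 0.74 (quartiles -0.25 and 1.61), while 6.7% of other probes rose. With an estimated correlation, adjusted p = 1.4e-06 for the ES-high group and 0.0098 for the PrEn-high group. The TS-high group (14 rose, 38 fell) and the P19-high group (9 rose, 41 fell) were called lower by camera, and these calls were lost at adjusted p = 0.23 and 0.085 with an estimated correlation. The NS1-high, placenta-high, fibroblast-high, TS and placenta-high and N2-high groups had no call. In total 2320 probes rose and 3198 fell against day 0. Of the fallers, 774 were well above background on both day 0 arrays and on neither day 5 array, and 92 risers showed the opposite. The day 0 arrays had 26165 and 27628 probes well above background and the day 5 arrays 24676 and 23446. Part of this imbalance may therefore reflect detection. Probe Z00076164-1 (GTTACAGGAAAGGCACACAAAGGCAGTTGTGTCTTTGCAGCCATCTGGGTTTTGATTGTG) fell 910-fold, from 5.31 ± 0.01 to -4.52 ± 0.08 (SD, n = 2 each), with adjusted p = 1.7e-38. Probe Z00031486-1 (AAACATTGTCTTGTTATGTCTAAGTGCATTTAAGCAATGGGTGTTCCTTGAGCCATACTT) rose 51.8-fold, with adjusted p = 1.6e-24. Day 5 was scanned on another day than days 0 to 4. Within 1 scan day, day 4 against day 0 had 2112 probes up and 3005 down, of which 1640 and 2668 were also called at day 5. The median of the PrEn-high probes was 0.26 in place of 0.74 with the local background kept at every spot, and 1.21 with the authors' table.

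In the PrEn course, 5G6GR5-high probes rose and ES-high probes fell against F9. Of the 62 5G6GR5-high probes, 31 rose and 2 fell by day 5, with a median log2 change of 0.92 (quartiles 0.16 and 2.30), and 8.4% of other probes rose. Of the ES-high probes, 178 fell and 13 rose, with a median of -1.03. With an estimated correlation, adjusted p = 0.00015 for the 5G6GR5-high group and 0.0042 for the ES-high group. Of the TS and placenta-high probes, 75 rose and 3 fell, of the placenta-high probes 117 rose and 21 fell, and of the fibroblast-high probes 47 rose and 10 fell. These 3 groups were called higher by camera, and the calls were lost at adjusted p = 0.12, 0.12 and 0.57 with an estimated correlation. The TS-high, NS1-high, N2-high and P19-high groups had no call. In total 2905 probes rose and 1359 fell against F9. Of the risers, 389 were not well above background on either F9 array and well above it on both day 5 arrays. The opposite held for 19 fallers. The F9 arrays had 23023 and 25052 probes well above background and the day 5 arrays 28401 and 27256, so detection may add to this imbalance. Probe Z00062597-1 (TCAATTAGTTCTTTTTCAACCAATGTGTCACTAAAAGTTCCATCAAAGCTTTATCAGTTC) rose 153-fold, from -1.51 ± 0.23 to 5.75 ± 0.24 (SD, n = 2 each), with adjusted p = 2.1e-31. Probe Z00021695-1 (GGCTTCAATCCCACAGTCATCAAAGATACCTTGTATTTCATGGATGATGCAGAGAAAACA) fell 24.4-fold, with adjusted p = 1.6e-28. F9 and PrEn were scanned on different days, so scan day and the difference from F9 cannot be told apart by the design. Within 1 scan day, PrEn day 5 against day 1 had 3256 probes up and 2109 down, of which 1766 and 792 were also called against F9.

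P19 is an EC line that forms neural cells after aggregation with retinoic acid. After 4 days of culture as aggregates with 1 µM retinoic acid, N2-high and NS1-high probes rose and ES-high probes fell against untreated cells. No group of aggregates without retinoic acid was included, so aggregation and retinoic acid cannot be told apart by the design. Of the 204 N2-high probes, 128 rose and 6 fell, with a median log2 change of 1.49 (quartiles 0.73 and 2.49), and 8.2% of other probes rose. Of the NS1-high probes, 165 rose and 22 fell, with a median of 0.50, which was 0.82 with the processed signals and 0.83 with the authors' table. Of the ES-high probes, 169 fell and 11 rose, with a median of -0.97. With an estimated correlation, adjusted p = 2.0e-07, 4.2e-05 and 0.0022 for these 3 groups. The calls of the TS-high group (17 rose, 40 fell) and the fibroblast-high group (42 rose, 15 fell) were lost at adjusted p = 0.15 and 0.70 with an estimated correlation. The placenta-high, TS and placenta-high, PrEn-high and 5G6GR5-high groups had no call. In total 2909 probes rose and 2167 fell, on arrays scanned on 1 day. Probe Z00036630-1 rose 162-fold, with adjusted p = 1.1e-36, and probe Z00034687-1 fell 123-fold, with adjusted p = 5.2e-34. Across probes the change correlated with that of N2 at day 6 at Pearson r = 0.64. Both comparisons called 1731 probes up, where independent lists would share 304.4, and 1146 down, against 169.8, while 119 were called in opposite directions.

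The timing of the loss of ES-high expression differed in size between the courses. At day 1 the mean log2 change of the ES-high probes was -0.48 ± 0.02 in N2, -1.16 ± 0.02 in ZHBTc4, -1.86 ± 0.02 in 5G6GR5 and -0.26 ± 0.00073 in PrEn (SD, n = 2 each). By day 5 the means were -3.01 ± 0.06, -2.77 ± 0.19, -3.18 ± 0.02 and -1.01 ± 0.0056. Each SD in this paragraph is of the later arrays around a fixed day 0 mean and leaves out the day 0 spread. For ES-high probes the SD of the day 0 arrays was 0.048 for ES_129b, 0.0066 for ZHBTc4, 0.027 for 5G6GR5 and 0.064 for F9. The PrEn changes and that of 5G6GR5 at day 5 also cross scan days. The difference between courses in these means was not tested. F9 cells, the day 0 of PrEn, had a mean log2 ratio of 0.27 for these probes, below the 0.92 to 1.73 of the 4 ES lines. The TS and placenta-high probes reached a mean of 0.73 ± 0.03 at 24 h and 2.41 ± 0.11 at 120 h in ZHBTc4. The NS1-high probes rose from 0.11 ± 0.03 at day 1 to 0.96 ± 0.04 at day 6 in N2.

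**Figure D2:**
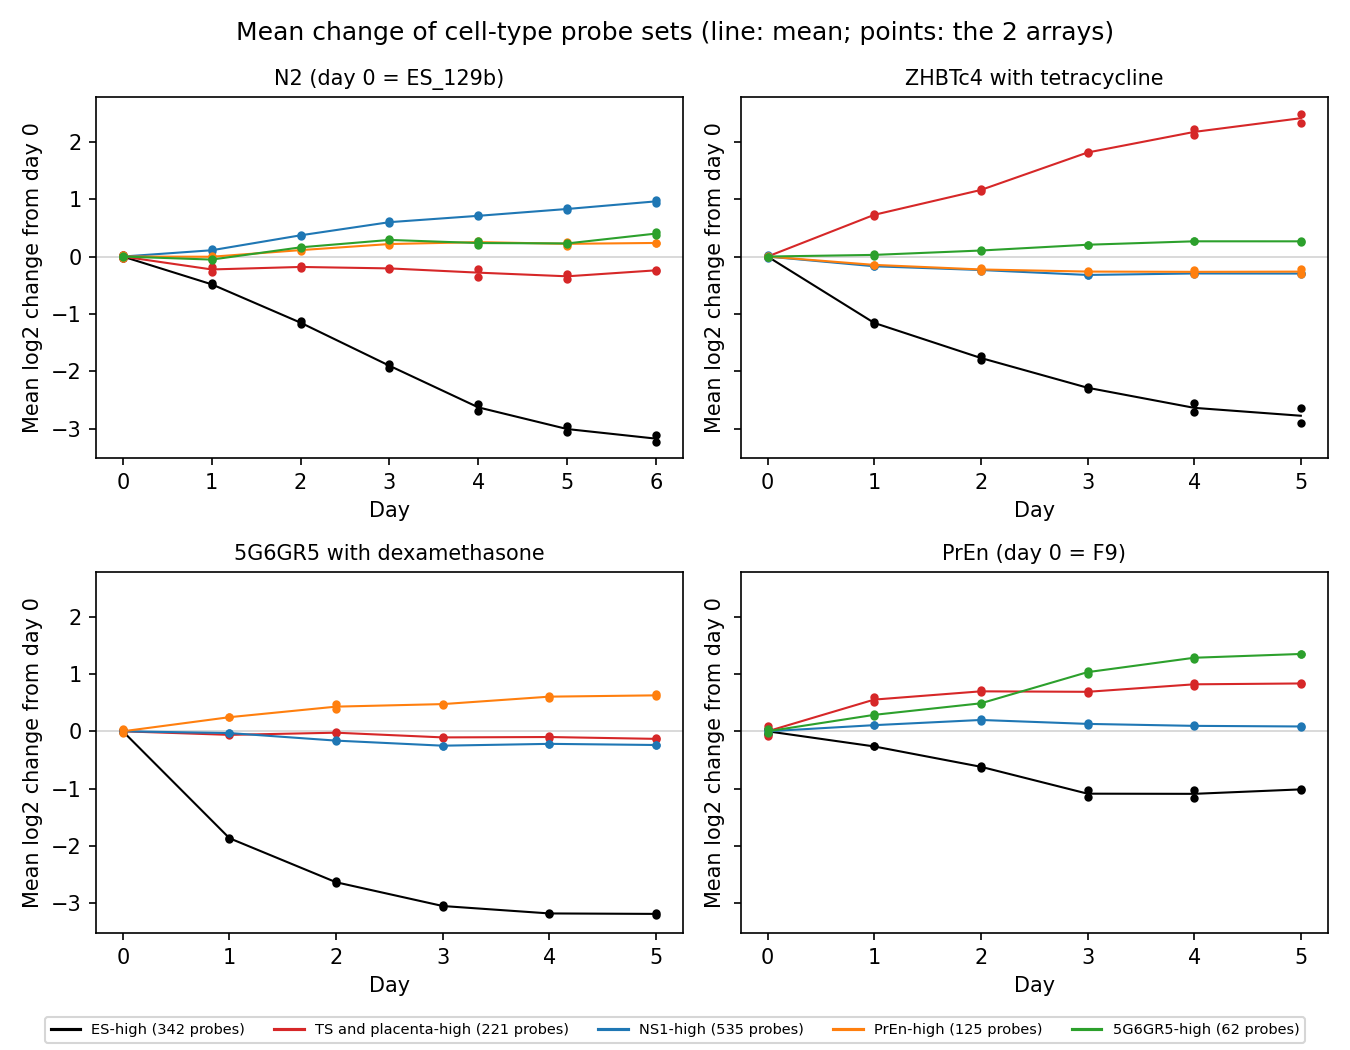
Mean log2 change from day 0 of 5 probe groups in the 4 courses, by day; lines join the means and points are the 2 arrays of each group, with the group defined from a course left out of its own panel. ES-high probes fall in all 4 panels, to -3.18 by day 5 in 5G6GR5 and -1.01 in PrEn, and the TS and placenta-high probes reach 2.41 in ZHBTc4.

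The courses were compared at day 5 by testing the difference of their changes from day 0. ZHBTc4 and 5G6GR5 differed at 8079 probes. Of these, 4946 had a more positive change in ZHBTc4, which can be a smaller fall, and 3133 a more negative one. The balance turned with Cy3 alone (4244 up, 4314 down) and with the processed signals (5688 up, 6120 down). ZHBTc4 and N2 differed at 9781 probes (5064 more positive in ZHBTc4, 4717 more negative). That balance turned with Cy3 alone (4837 up, 5240 down), the processed signals (5720 up, 8060 down) and the authors' table (4207 up, 4534 down). 5G6GR5 and N2 differed at 6047 (2466 more positive in 5G6GR5). The 3 courses shared more fallers than risers, although within N2 and within ZHBTc4 more probes rose than fell at day 5. In all 3 courses 825 probes fell at day 5, where independent lists would share 25.3. In all 3 courses 303 rose, where independent lists would share 27.2. The 3 courses share no day 0 arrays. Of the 825 common fallers, 253 were ES-high probes, and 361 also fell in PrEn and 353 in P19 with retinoic acid. Lower than in ES lines were 630 of them in fibroblasts, 599 in TS cells and 693 in NS1 cells. Of the 303 common risers, 220 also rose in PrEn and 168 in P19 with retinoic acid. Higher than in ES lines were 217 of them in fibroblasts, 193 in TS cells and 219 in NS1 cells. Restricted risers, which rose in 1 course and rose more there than in each of the other 2 by the test of the difference, numbered 2551 in ZHBTc4, 505 in 5G6GR5 and 1356 in N2. Of the 2551 in ZHBTc4, 1628 were also higher in placenta, 1075 in TS cells and 516 in NS1 cells than in ES lines. Of them 484 rose in PrEn and 241 in P19 with retinoic acid. Of the 505 in 5G6GR5, 248 also rose in PrEn and 71 in P19 with retinoic acid. Higher than in ES lines were 165 of them in placenta, 113 in NS1 cells and 100 in TS cells. Of the 1356 in N2, 729 also rose in P19 with retinoic acid and 264 in PrEn. Higher than in ES lines were 699 of them in NS1 cells, 249 in placenta and 219 in TS cells. Among all tested probes, 3833 were higher in TS cells and 5114 in NS1 cells. In PrEn 2905 of all probes rose and in P19 with retinoic acid 2909. Changes of 5G6GR5 and PrEn at day 5 correlated at Pearson r = 0.48 across probes, with 1168 probes up in both (197.6 by independent lists) and 852 down in both (127.4). With N2 taken at day 6 and the others at day 5, the other pairs correlated at r = 0.45 for N2 with 5G6GR5, 0.43 for ZHBTc4 with 5G6GR5, 0.36 for N2 with PrEn, 0.34 for ZHBTc4 with PrEn and 0.24 for N2 with ZHBTc4.

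NS1 cells are dividing cells from forebrain neurospheres, and DC are differentiated neural cells, which the labels derive from NS5 cells rather than from NS1. DC and NS1 were scanned on 1 day and labelled with different kits. In DC 2813 probes were higher and 2523 lower than in NS1. Of those higher, 267 were well above background on both DC arrays and on neither NS1 array, and 65 of those lower showed the opposite. The DC arrays had 28561 and 27018 probes well above background, against 24390 and 25532 for NS1, which may add to this imbalance. Probe Z00035254-1 was 124-fold higher in DC, with adjusted p = 1.4e-36, and probe Z00034979-1 was 91.8-fold lower, with adjusted p = 4.0e-37. The difference between DC and NS1 correlated with the N2 change at Pearson r = 0.08 and Spearman rho = 0.14 across probes. Both called 661 probes up, where independent lists would share 294.4, and 275 down, against 197.7, while 582 were called in opposite directions. The replicates of DC and NS1 were the least alike of the 44 groups, at r of 0.913 and 0.906. The SD of their replicate differences (log2) was 0.58 and 0.55, against a median of 0.18 over the groups. The count depended on the processing. It was 884 in total when the 4 arrays alone were fitted, and 3012 with the ratios scaled between arrays. The smaller fit leaves 2 residual degrees of freedom in place of 44, which alone does not account for the drop. Fitted likewise on 4 arrays, N2 had 6230 calls against 6241, and P19 with retinoic acid 4926 against 5076. The spread shared by all groups may thus be too small for DC and NS1. The counts and p-values given for DC against NS1 may be overstated. NS1 cells differed from the 4 ES lines at 5114 higher and 4535 lower probes, the largest number of the planned cell comparisons against ES lines. More were lower than higher with Cy3 alone (4851 up, 4989 down) and with the authors' table (4694 up, 5000 down). Probe Z00031516-1 was 145-fold higher in NS1, with adjusted p = 8.2e-31. The N2 change at day 6 correlated with this difference at r = 0.62, up from 0.19 at day 1. Both called 1903 probes up, where independent lists would share 535.2, and 1967 down, against 355.3. With fibroblasts against ES lines it correlated at r = 0.53, up from 0.12 at day 1, with 1428 probes up in both and 1769 down in both.

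TS cells, from the extraembryonic lineage that forms the placenta, had 3833 probes higher and 3070 lower than the ES lines. Probe Z00057509-1 was 98.3-fold higher in TS cells, with adjusted p = 1.7e-40. Probe Z00034687-1 was 433-fold lower, with adjusted p = 1.3e-43, and this same probe had the largest fall named in NS1 (455-fold, adjusted p = 4.4e-44), in fibroblasts (349-fold, adjusted p = 5.4e-09) and in P19 with retinoic acid. E12.5 placenta had 4749 probes higher and 2848 lower than TS cells, a balance that turned with Cy3 alone (3755 up, 4167 down). Of the higher probes, 1063 were well above background on both placenta arrays and on neither TS array, by a median of at least 3.17-fold. The opposite held for 174 of the lower ones. The placenta arrays had 26013 and 27691 probes well above background, against 24712 and 25228 for TS, which may add to this imbalance. Probe Z00031231-1 was 1405-fold higher in placenta, at a log2 ratio of 7.26 ± 0.12 against -3.19 ± 0.02 (SD, n = 2 each), with adjusted p = 2.1e-44. TS, NS1, placenta and the ES lines were scanned on different days, apart from TS and NS1, so day and cell type cannot be told apart by the design. On the scan day of TS and NS1, TS differed from ZHBTc4 ES cells at 0 h at 4359 higher and 3942 lower probes. Of these, 2765 and 1978 were also called against the ES lines. NS1 differed from ZHBTc4 at 0 h at 4960 higher and 4608 lower, of which 3738 and 3080 were shared. NS1 and ZHBTc4 were labelled with different kits, so this comparison still crosses kits.

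Cell classes were compared with the line as the replicate. The 4 fibroblast lines or strains differed from the 4 ES lines at 3762 higher and 3330 lower probes, a balance that turned with the processed signals (5067 up, 5809 down), Cy3 alone (3672 up, 3681 down) and the authors' table (3402 up, 3600 down). Probe Z00025893-1 was 194-fold higher in fibroblasts, with adjusted p = 2.7e-05. The 2 EC lines, F9 and P19, differed from the ES lines at 128 higher and 321 lower probes. The total for EC was 101 when only EC and ES lines were fitted and 295 with scaling between arrays. With the processed signals it was 794 (395 up, 399 down). Probe Z00075970-1 was 7.44-fold higher in EC lines, at 3.00 ± 0.23 (SD, n = 2) against 0.10 ± 0.09 (n = 4), with adjusted p = 4.7e-07 by limma. The ES-high probes had a mean log2 ratio of 0.27 in F9 and -0.64 in P19, and from 0.92 to 1.73 in the ES lines. The count for EC was 1484 without F9 and 224 without the ES line ES-D3-GL. It rose to 681 without replicate 1 of EBRTcH3. In EBRTcH3, ES-D3-GL and the EG line TGC_8.5-5 the 2 arrays of a line were labelled with different kits. With the arrays of the kit used for the EC lines alone (2 ES and 2 EC lines) no probe was called by limma. In that fit 3651 had an unadjusted p below 0.05. It leaves 2 residual degrees of freedom in place of 9, so its lack of calls does not show kit to be the cause. By the design, scan day and class cannot be told apart for these comparisons, since fibroblasts, EC, iPS and ES lines were scanned on different days. The ES and EG lines shared 1 scan day. Against the same ES arrays, in the same fit and across days, fibroblasts had 7092 calls, EC lines 449 and iPS lines 2. EC and iPS lines were scanned on other days than fibroblasts and had 2 lines each against 4. These counts therefore do not measure an effect of the fibroblast day, which held no other cells. For fibroblast, EC and iPS lines scan day stays open.

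The iPS and EG lines had few or no called differences from the ES lines when the arrays of both labelling kits were used. By limma 2 probes were higher in the 2 iPS lines and none lower, with 2296 at an unadjusted p below 0.05. The iPS count was 0 when only iPS and ES lines were fitted, 108 with the processed signals and 30 with the authors' table. Probe Z00029964-1, named after its value was seen, was called higher in iPS lines with adjusted p = 0.0042. It was well above background on all 4 iPS arrays and on 1 of the 8 ES arrays, so no fold is given. Probe Z00068862-1 was 2.68-fold higher, with adjusted p = 0.028. With the arrays of the low-input kit alone, the kit of both iPS lines, 54 probes were higher and 37 lower in iPS lines. The iPS count was 31 without replicate 1 of EBRTcH3 and 24 without that line. It was 1 without ES-D3-GL, 20 without iPS-MEF-FB-20A-10, 70 without iPS-MEF-Ng-38C-2, 9 without replicate 1 of the latter and 5 without replicate 1 of the former. It was also 5 without replicate 1 of ES-C57BL6.9 and 4 without replicate 2 of ES-D3-GL. By limma no probe differed between the 2 EG lines and the ES lines, with 581 at an unadjusted p below 0.05. Chance alone would give more than 581 among 34105 tested probes, so the test may be too strict here. The lack of calls thus does not show the EG and ES lines to be alike. On data simulated at these sizes, 89% of probes changed 2.83-fold and 86% of those changed 4-fold were recovered for iPS lines, with 3 false calls. That simulation gave every line the spread among the 4 ES lines. The fit to the data also pools the spread among fibroblast and EC lines, so it may recover fewer. Across probes, the iPS difference from ES lines correlated with the fibroblast difference at r = 0.36, against 0.41 for simulated unchanged lines that share the ES lines as controls. The covariance was 0.14, against 0.025 simulated. With the ES lines split so that no control was shared, r was 0.26 on average over 6 splits (0.15 to 0.39). For EG the split mean was 0.10 (-0.09 to 0.30), and for EC it was 0.22 (0.13 to 0.32). The splits do not remove scan day: all ES lines shared 1 day with the EG lines, while fibroblast, iPS and EC lines had other days. All fibroblast and iPS arrays were also of the low-input kit, while the ES arrays were of both. A day or kit difference from the ES lines can therefore still be common to both sides.

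ES_129a and ES-129.3 carry the same line name in the labels, so their difference measures cultures, RNA preparation, labelling kit and scan day rather than cell type. ES_129a had 152 probes higher and 503 lower than ES-129.3. Probe Z00070458-1 was 25.8-fold lower in ES_129a, with adjusted p = 1.1e-22, and this probe also had the largest rise named in fibroblasts against ES lines (294-fold, adjusted p = 0.00016). Within 1 scan day, the ES groups ES_129b and ES_129a differed at 93 probes.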

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

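The differences between courses at day 5 were found by a test of the difference itself on all probes tested. ZHBTc4 and 5G6GR5 differed at 8079 probes, ZHBTc4 and N2 at 9781, and 5G6GR5 and N2 at 6047. The reference channel of the same arrays differed at 273, 232 and 114 probes. The comparison of ZHBTc4 with N2 runs between 2 scan days, but each of these courses was measured against a day 0 of its own scan day; 5G6GR5 at day 5 was scanned on another day than its day 0.

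In the ES line EBRTcH3 the TS and placenta-high probes had a mean log2 ratio of -0.75, lower than in the other 3 ES lines, of which the nearest was at -0.45. The gap was 0.98 of the range of the 4 lines, beyond the limit that chance passes in about 1 in 20 groups of lines; 12 were examined. The replicates of EBRTcH3 correlated at r = 0.91 and were labelled with different kits.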

How the results depend on the processing

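The local background at every spot was the setting planned before the data were examined; the outlier-background step, the fixed slide block, the labelling kit settings and the fit without DC and NS1 were chosen after seeing the data. No named probe, probe group median or correlation examined changed sign under the processing settings. Only a part of the group medians and correlations given above was examined. Over 72 combinations of a group median with a setting, 44 moved beyond the spread between arrays and 28 did not. The larger of the up and down counts changed side under at least 1 of processed signals, Cy3 alone and the authors' table for ZHBTc4, PrEn, TS, placenta, NS1, fibroblasts, ZHBTc4 minus 5G6GR5 and ZHBTc4 minus N2. Feature Extraction processed signals without loess gave more calls: N2 10578, ZHBTc4 12724 (5440 up, 7284 down), 5G6GR5 9736, PrEn 8359 (3579 up, 4780 down), P19 8398, TS 11728 (4774 up, 6954 down), placenta 11857, NS1 15197, ES_129a against ES-129.3 2042 (776 up, 1266 down), 5G6GR5 minus N2 9239, fibroblasts 10876, iPS 108, EG 1 and EC 794 (395 up, 399 down). Its splits were 5688 and 6120 for ZHBTc4 minus 5G6GR5 and 5720 and 8060 for ZHBTc4 minus N2. It moved the median of all probes by -0.26 to 0.14 (log2), by over 0.1 in 7 of 13 comparisons; the authors' table and Cy3 alone did so in 1 each. Cy3 alone gave splits of 2505 and 1954 for PrEn, 3755 and 4167 for placenta, and 4244 and 4314 for ZHBTc4 minus 5G6GR5, and iPS 1. The authors' table gave ES_129a 1403, iPS 30 and for PrEn 2916 up and 2104 down. The iPS count was 13 without background subtraction, 10 with scaling and 4 without a filter. Scaling gave DC 3012 and EC 295. Fits of only the arrays or lines compared, with fewer samples, gave DC 884, iPS 0 and EC 101. Fewer samples alone do not account for the DC count, since such a fit gave 6230 for N2, against 6241. Arrays as replicates, which count each line more than once, gave iPS 588 (355 up, 233 down), EG 202 and EC 1985. Arrays of 1 labelling kit gave iPS 91 (54 up, 37 down) and EC 0, the latter with fewer lines. Kit as a block, estimated from the 3 lines with both kits, gave DC 5679, TS 6834, NS1 9749 and ES_129a 723. The cause of the other shifts was not tested.

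With the planned background 5G6GR5 had 4812 calls and P19 3816. Leaving out 1 array gave 2 to 31 calls for iPS, 304 to 681 for EC and 0 for EG; leaving out 1 line gave 1 to 70, 224 to 1484 and 0 to 14. A lone array or line is then assumed to vary like the others. Leaving out 1 array or line moved no other count by over 1.5 times. The replicate block changed no count by over 1.5 times (N2 6201, ZHBTc4 8110, 5G6GR5 5502, PrEn 4289, P19 5045, DC 5287); the numbers of 5G6GR5, with 1 of 3 pairs above 0.1, and of P19 and DC with NS1, with 1 pair of groups each, are shared numbers only. Slide as a random block (correlation -0.083) gave 6200 for N2. As a fixed block slide could be fitted for 2 comparisons, at 6285 for N2 and 5283 for DC. Scan day as a random block could not be fitted, since every group lay within 1 day; the mean over probes of a gene was not run, since probes are unnamed. Signal over background limits the dimmest probes, for which folds are bounds.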

Other observations

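Of the tests below, those of feeder cell RNA, of scan day and of the labelling kit were chosen after the result was seen. Some probes changed within a course and moved back. In N2, 424 probes rose at an intermediate day, were lower at day 6 than on that day by the same test and were not called up at day 6, and 113 did so in the opposite direction. The numbers were 304 and 289 in ZHBTc4, 280 and 219 in 5G6GR5, and 696 and 881 in PrEn. PrEn was measured against F9, an assumed start scanned on another day. An offset of F9 can therefore pass for a change that moved back. In 5G6GR5 the step back to day 5 crosses scan days. In PrEn, 1483 probes were up and 1444 down at day 1 against F9, and 1986 rose and 451 fell from day 1 to day 2. Of the day 5 risers in PrEn, 19.6% were past the threshold at day 1, against 19.3% in 5G6GR5 and 15.9% in ZHBTc4; of the day 6 risers in N2, 3.25% were. Of the day 5 fallers in 5G6GR5, 45.7% were past it at day 1.

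The fibroblast-high probes had a mean log2 ratio of -1.56 in ES-129.3 and of -1.56 in iPS-MEF-FB-20A-10, against -2.07 to -2.23 in the other 3 ES lines and -1.91 in iPS-MEF-Ng-38C-2. Among the 4 ES lines the gap of ES-129.3 to the nearest line was 0.76 of the range, which did not pass the bound for an outlying line. The iPS values were not tested.

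The fibroblast and ES lines differed at 7092 probes. Only the real grouping among the 35 splits of the 8 lines gave as many (1 of 35). The highest count of another split was 0. Every other split mixes fibroblast and ES lines on both sides, which puts the difference between them into the spread. A rank of 1 of 35 is the most extreme that this test can give, so it cannot exclude chance.

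The 655 probes that differ between ES_129a and ES-129.3, which share a line name, may reflect RNA of fibroblast feeder cells in the ES-129.3 cultures. Of 406 probes high in fibroblasts against the other 3 ES lines, 22.4% (91) were higher in ES-129.3, against 2.14% of 468 probes high in TS cells and 1.39% of 647 high in NS1 cells. These 3 groups were defined for this test, without ES-129.3 and without placenta, and are not those of the same sources used elsewhere. That share, the first test, lay between the values fixed for and against feeder RNA, and the tests of the lower and higher probes were added after it was seen. The excess of the 406 corresponds to a median feeder share of 4.44% (quartiles 1.81 and 9.39). Feeder RNA is argued against as the cause of the 152 probes lower in ES-129.3: a 2-fold dilution needs feeder RNA as at least an equal part, and 1.97% (8) of the 406 probes reached the level of an equal mixture. It is argued against as the whole cause of the 503 higher probes, if feeders resemble the 4 fibroblast lines: 12.7% (64) were over 2-fold above every one of these lines in ES-129.3, which a mixture cannot give, against a bound of 10%. A part in the other higher probes stays open, since 350 of the 503 were at least 2-fold higher in the fibroblast lines than in ES_129a, and 91 were among the 406. Scan day alone is argued against, since the reference channel of the same arrays differed at 35 probes; the labelling kit may contribute, with r = 0.34 between this difference and the mean kit difference within EBRTcH3, ES-D3-GL and TGC_8.5-5, but 723 probes were called with kit as a block. The test of kit first planned treated EBRTcH3 and ES-D3-GL as lines of 1 kit, which the labels contradict, and its r of 0.14 decides nothing.

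The replicates of NS1 and of DC differ more than those of most groups. Dim probes are argued against as the cause, since among probes above the median Cy3 level the SD of the NS1 replicate difference was 0.64, against a median of 0.18 in other groups. A different share of differentiated cells may contribute: the NS1 replicate difference correlated with DC minus NS1 at r = 0.15, between the values fixed for and against it, so this stays open. The replicate differences of NS1 and DC correlated with each other at r = 0.35. No other biological explanation was tested.

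The differences between the arrays of the 2 kits correlated between these 3 lines at r of 0.54 to 0.61 across probes, where probes are not independent replicates. In each of these 3 lines the labels give a passage number for the array of the other kit and none for the low-input array. Whether the arrays of the 2 kits also came from different cultures is not given in the labels.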
